A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

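The study used 2-colour splicing-sensitive microarrays of budding yeast RNA. Each array compared cells whose only PRP8 gene carried the S2197F change with cells whose only PRP8 gene was wild type, per the labels. Both genes sat on a centromeric plasmid in strains lacking the chromosomal copy. Per the labels' protocols, cells were grown in rich medium at 37 °C to an OD600 of about 0.7, RNA was extracted with hot phenol, and cDNA was made with random primers. The cDNA of each RNA was divided between Cy3 and Cy5, so every pair of cultures was hybridised on 2 arrays with the dyes exchanged. There were 3 independent pairs of cultures and 6 arrays. The 2 arrays of a pair carry the same RNA and count as 1 biological replicate, so n = 3 throughout, and wild type is the other channel of the same arrays.

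The values tested are log ratios from the authors' deposited table, taken here as log2, with positive values meaning more RNA in the mutant. Per the labels, the authors analysed each array together with its dye flip and gave 1 value per biological replicate. The table has 253 rows for 239 genes, and 10 genes have more than 1 row. Each row holds an exon, an intron and a junction feature, which the labels call total mRNA, pre-mRNA and mature mRNA. The image analysis, background correction, spot filter and normalization behind these values are not given in the sources used here. The base of the logarithm is not stated either. The deposited single-array values stop at 16.61, which is log2 of 100000, and the table tested was assumed to have the same base. The heights of the 2 tables do not settle this, because they are alike only if replicate 1 of the single-array values is turned against its titles, which is an open question in the closing section. All fold changes depend on the assumption. An intron feature also hybridises to splicing intermediates and excised introns, so "pre-mRNA" is the labels' name for it and not a measurement of unspliced transcripts alone.

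A second table holds single-array log2 ratios for 9216 spots on each of the 6 arrays, as deposited by the authors. Its spots have positions and no gene names, so it was not used for genes. Its array medians ran from -0.82 to 0.22, and its normalization and direction are unknown. Values 8 rows apart within a print block correlated at a mean r of 0.58 across the arrays, and values at the other spacings examined at no more than 0.12. Spots were therefore averaged over 3 prints per feature, although the series' design text speaks of fewer. These averages served only for checks of the arrays in the closing section. The authors' table of means over the replicates adds no information and was not used.

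Features with values in at least 2 replicates were tested with limma 3.58.1 in R 4.3.3, as a one-sample model of the log2 ratio against 0 with empirical Bayes variances, two-sided. The 3 classes shared 1 fit, and p was adjusted by the Benjamini-Hochberg method within each class, at a threshold of 0.05. This covered 251 intron, 248 junction and 234 exon features. Differences between 2 classes of the same row and replicate (intron minus junction, intron minus exon, junction minus exon) were tested in the same way, each in a fit of its own. Such a difference does not depend on how an array was centred. The SE given for a feature is limma's moderated SE. A median over features is given as mean ± SD of the 3 replicate medians. An exact sign-flip test of 3 values cannot give a two-sided p below 0.25, so medians are described by size and spread. Ribosomal protein genes were compared with other genes, at 1 value per gene, by the difference of medians in each replicate, given as mean ± SD. The difference between the medians of the genes' means over replicates, which is another value, was tested by a two-sided permutation that reassigned gene labels 100000 times. Genes are not independent replicates, and those p-values describe these arrays. They were adjusted over 6 such comparisons.

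Of 21 gene lists fixed before the data were examined, 9 had at least 4 measured genes: ribosomal protein genes, hosts of intronic snoRNAs, genes with 2 introns, meiosis, the actin and tubulin cytoskeleton, secretory traffic, ubiquitin and proteasome, mitochondria, and RNA processing. Each was tested in each class with limma's camera at a preset correlation of 0.01, adjusted over 27 tests. Camera sets a list against the remaining features, so its direction can differ from the sign of the list's median. Camera with an estimated correlation and fry were alternatives. All of these list tests used only features with values in every replicate. The genes named were also set by a rule fixed then. They are ACT1, up to 5 features with the highest and 5 with the lowest mean ratio among those past the threshold with the same sign in all 3 replicates, per class and for the intron minus junction difference, and up to 4 members of each list with the largest ratio in size. PRP8 and HIS3 were on the rule but are not in the table used here. The result of 1 gene that the rule names is not reported here, in the text or in the plots of single genes. Any other gene named was chosen after its values were seen, and this is said where it occurs.

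Gene names are those of the table. A reference gene table of the R64 assembly, used for names only, matched 236 of the 239 genes, and 10 of these have another current symbol there. No genome sequence was used, so splice site sequences, intron lengths and genomic positions were not analysed here. Where a gene has more than 1 row, the table does not say which intron each row stands for, and rows are called first and second in the order of the table.

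The number of arrays limits the precision, and signal over background was not analysed here. The procedure was tested on simulated data, drawn independently for each feature with limma's moderated SD from the real fit. Such data meet the assumptions of the test. The recoveries and false calls below therefore do not show how it fares with the replicate spread of single features or with correlated genes. With a shift of 0.5 in log2, 6 of 20 shifted intron features, 5 of 20 junction features and 10 of 20 exon features were recovered. All 20 were recovered in each class at a shift of 1 or 1.5. Among unshifted features, 1 of 191 intron, 3 of 188 junction and 1 of 174 exon features were called. In a separate simulation only ribosomal protein introns were shifted, by 0.5. Camera called that list and 1 of the 26 other tests of a list in a class. The snoRNA host and 2-intron lists hold some of the shifted introns, and the other intron lists were set against them. The count is therefore no rate of false calls. Alternatives left out each replicate in turn, centred each replicate on the median of its exon features, used only genes with complete values, used robust variances, fitted each class alone, and changed the threshold. Use of 1 value per gene, and removal of SNR17A and SNR17B, were added after the data were seen. Checks in the closing section used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.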

Results

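Prp8 is the large protein at the catalytic core of the spliceosome, and changes in its human counterpart cause retinitis pigmentosa, an inherited degeneration of the retina. The series asks how such a change, S2197F, affects splicing in budding yeast. RNA from mutant and wild type cells at 37 °C was compared on 6 arrays, which form 3 biological replicates, each a pair of independent cultures with its dye exchange. The table covers genes with introns, and the features for exon, intron and exon junction were read as total mRNA, pre-mRNA and mature mRNA. Values are ratios of mutant to wild type, assumed to be log2, as mean ± SE from limma, with n = 3 unless stated, and adjusted p-values are limma's after Benjamini-Hochberg adjustment.

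The first comparison asks which introns gave more signal in RNA of the mutant than in wild type. Intron signal rose in S2197F for 59 of 251 features and fell for 0, while 90 higher and 2 lower features had an unadjusted p under 0.05. SNR17B and SNR17A, the near-identical genes of the U3 small nucleolar RNA, had the highest ratios. The intron of SNR17B rose 4.76-fold (2.25 ± 0.15, adjusted p = 0.000125), with 2.27, 2.26 and 2.22 in the 3 replicates, and that of SNR17A rose 4.24-fold (2.08 ± 0.15, adjusted p = 0.000125). Probes for these copies cannot be assumed to tell them apart. TEF4, a subunit of translation elongation factor 1B, followed at 2.91-fold (1.54 ± 0.19, adjusted p = 0.0031). ASC1, a protein of the small ribosomal subunit, rose 2.47-fold (1.31 ± 0.22, adjusted p = 0.015), and so did YIP3, a membrane protein of vesicle traffic (1.30 ± 0.27, adjusted p = 0.021). The intron of ACT1, the actin gene often used to follow yeast splicing, rose 1.82-fold (0.86 ± 0.20, adjusted p = 0.024). All of these were higher in 3 of 3 replicates, which the rule for naming genes required of all but ACT1.

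Over all intron features the median ratio was 0.22, 0.29 and 0.38 in the 3 replicates (0.30 ± 0.08, SD, n = 3), a fold of 1.23. Of 245 introns measured in every replicate, 126 were higher in all 3 (51.4%) and 11 lower in all 3 (4.49%). Chance would give 12.5% each way only if the ratios of every replicate were centred on 0, and features of a replicate share its offset. Exon features were lower in all 3 for 33.3% and higher for 6.41%, and junction features for 29.7% and 6.85%. These shares therefore describe a shift of a class and are no test of single introns. The smallest ratio that passed was 0.51. Exon features had a median of -0.13 ± 0.06 (SD, n = 3) in the values as deposited. When each replicate was centred on its exon median, 91 introns passed, all higher, including all 59. Leaving out a replicate lowered the number that passed: without replicate 2 only SNR17A and SNR17B did, and without replicate 1 there were 35, of which 30 were among the 59. ACT1 missed the threshold without replicate 3 as well (adjusted p = 0.053). All 59 kept a ratio above 0 whichever replicate was left out.

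**Figure D1:**
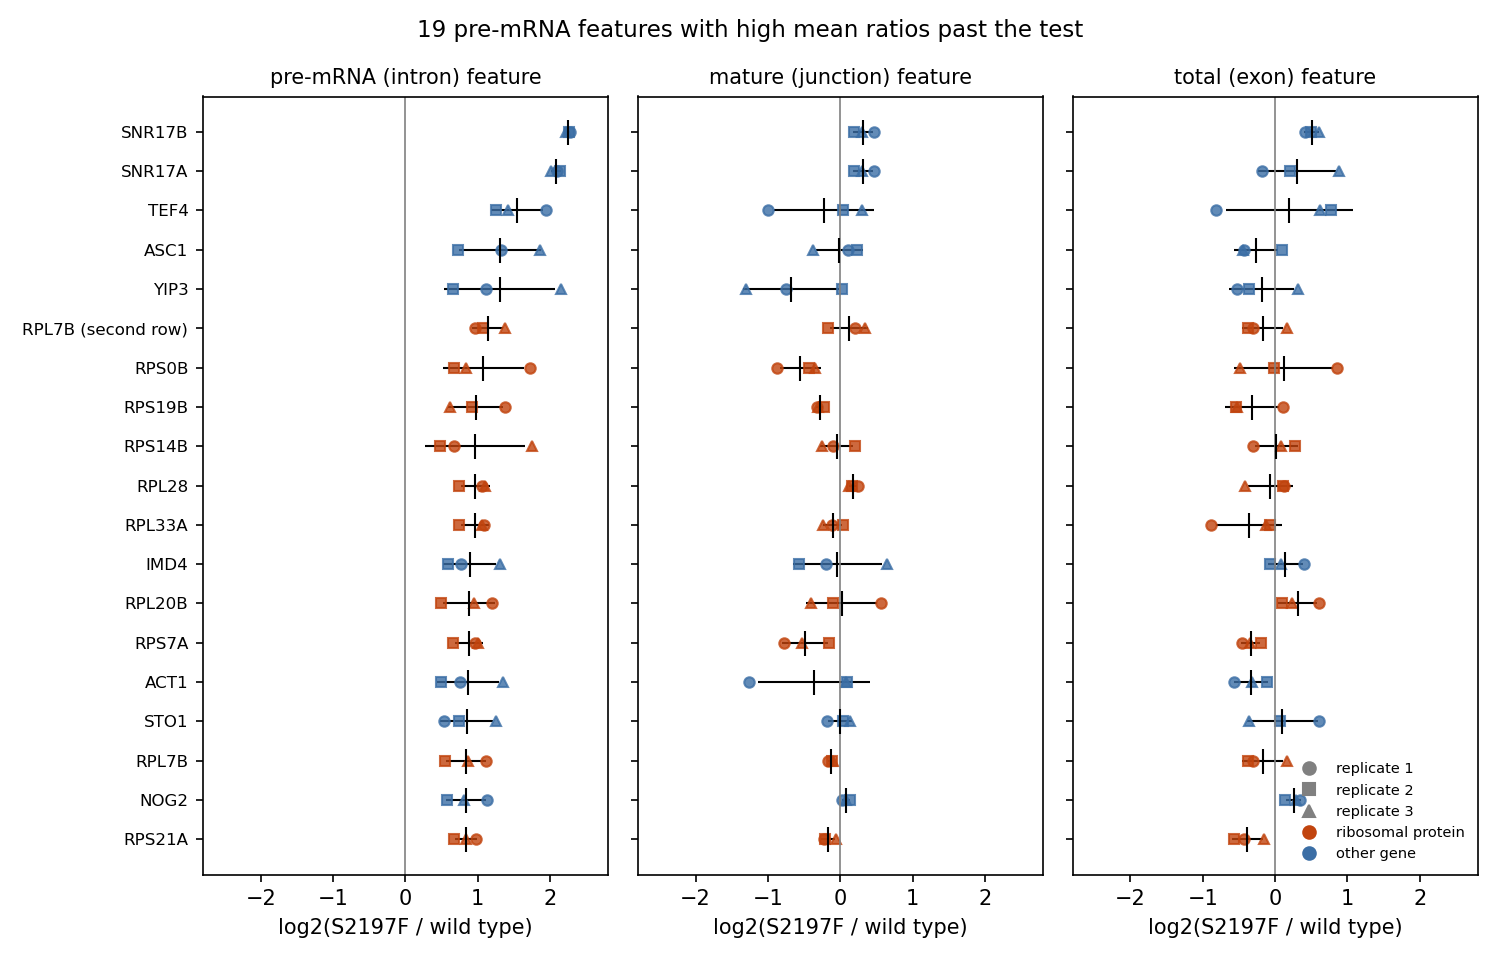
Log2 ratio of S2197F to wild type (x axis) for 19 intron features with high mean ratios among those past the test, with the intron feature at left and the junction and exon features of the same gene at centre and right; symbols are the 3 replicates, the vertical tick is the mean and the line spans 1 SD to each side. The features were picked for high intron means with the same sign in all 3 replicates, so intron values above 0 in every replicate follow from the choice. The intron means run from 0.83 to 2.25. Junction and exon values of the same genes, which were not used to pick them, lie on both sides of 0. SNR17A and SNR17B share 1 junction value.

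Introns of ribosomal protein genes, which carry much of the splicing load of growing yeast, made up most of those that rose. Among 101 such features 44 rose and 0 fell, and 59 rose when adjusted over the list alone. Among those reported here were the second row of RPL7B (1.14 ± 0.16, adjusted p = 0.0084, 2.20-fold), RPS0B (1.08 ± 0.22, adjusted p = 0.021) and RPS19B (0.97 ± 0.19, adjusted p = 0.021). By comparison 15 of 150 features of other genes rose. After centring on exon features the counts were 66 and 25. Of the introns measured in every replicate, 82 of 101 ribosomal protein features were higher in all 3 and 0 lower, against 44 of 144 higher and 11 lower for other genes.

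The median intron ratio of 98 ribosomal protein genes was 0.54, and that of 139 other genes 0.16, a difference of 0.38 (two-sided permutation of gene labels, p = 1e-05, the smallest it can give, adjusted p = 2e-05). Taken within each replicate the difference was 0.62, 0.24 and 0.16 (0.34 ± 0.24, SD, n = 3), and 0.20 on average without replicate 1. Calls were more frequent among ribosomal protein features (Fisher's exact test, odds ratio 6.89, 95% interval 3.44 to 14.5, p = 1.12e-09), although genes are not independent replicates. The list also stood above the other features by camera (adjusted p = 5.9e-10), but not with an estimated correlation (adjusted p = 0.87). Fisher's exact test did not pass without replicate 1, where 19 of 101 ribosomal protein and 16 of 144 other features rose (odds ratio 1.85, 95% interval 0.846 to 4.09, p = 0.098), or without replicate 2, where 0 and 2 did.

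**Figure D2:**
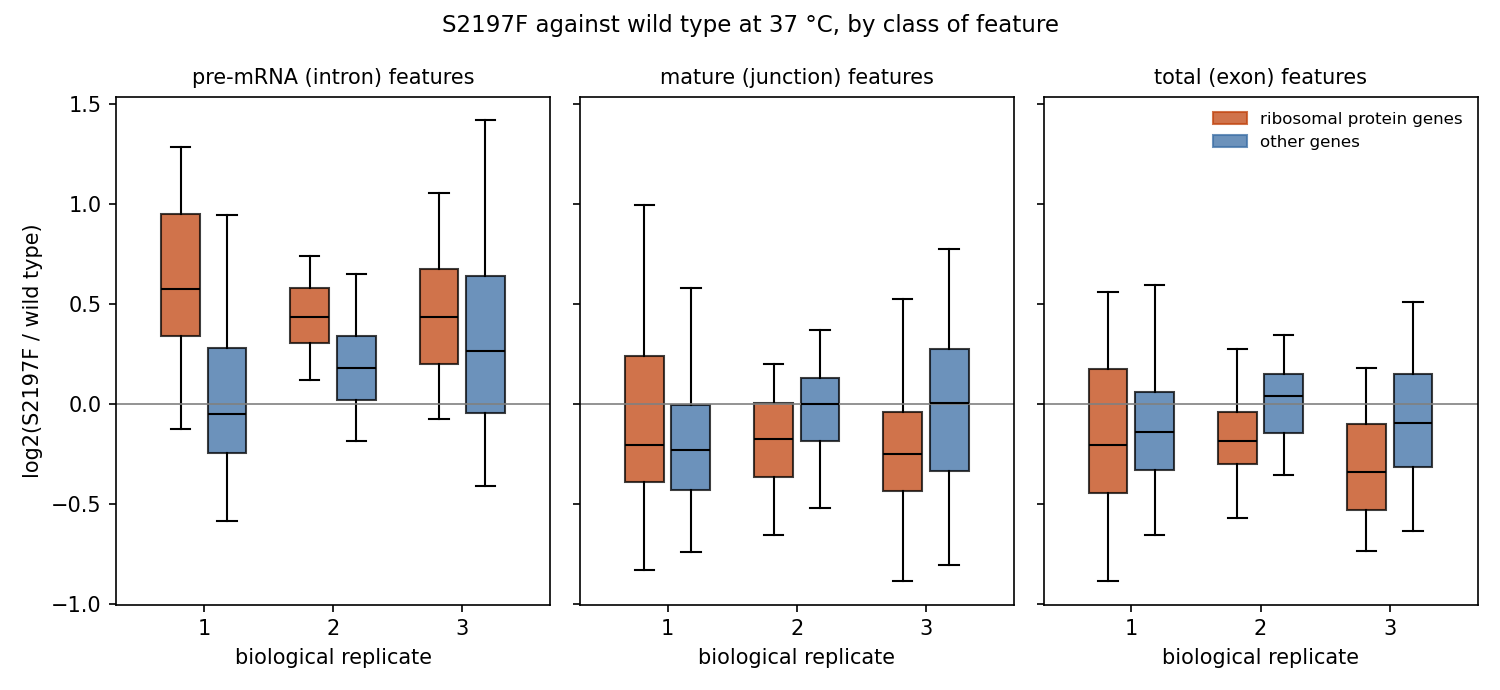
Log2 ratio of S2197F to wild type (y axis) in each biological replicate (x axis) for intron, junction and exon features of ribosomal protein genes and other genes. Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles; the intron boxes of ribosomal protein genes lie highest in every replicate, with a difference of medians from other genes of 0.62, 0.24 and 0.16 at 1 value per gene.

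Introns of genes that host intronic small nucleolar RNAs stood above the other introns by camera (adjusted p = 0.0091). They did not with an estimated correlation (adjusted p = 0.87). The list takes both rows of RPL7A, RPL7B and RPS22B, which are also ribosomal protein genes. Which of their rows is a host intron is not known here. Of 11 features from 8 host genes, 8 rose, also when adjusted over the list alone, and the median ratio was 0.84. TEF4, ASC1 and the second row of RPL7B led the list, followed by IMD4, an enzyme of guanine nucleotide synthesis (0.89 ± 0.19, adjusted p = 0.021). The 3 features that did not pass were the second row of RPL7A and both rows of RPS22B, the latter at 0.14 ± 0.18 and -0.04 ± 0.17 (adjusted p = 0.62 and 0.91). None of the 11 features passed without replicate 2 (0 calls). SNR17A and SNR17B are not on this list.

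Introns of meiosis genes, which are little expressed in cells growing in rich medium, did not pass. Of 9 features 0 did so, over all introns or over the list alone. Their median of -0.02 was below that of other introns by camera (adjusted p = 0.027; adjusted p = 0.87 with an estimated correlation; adjusted p = 0.26 without replicate 1). Camera covered the 8 of these features with values in every replicate, which leaves out DMC1. Over these 8 the median was 0.12 after centring on exon features, and the mean as deposited was 0.01. The members with the largest ratios were DMC1, the meiotic strand exchange protein (-0.28 ± 0.20, n = 2, adjusted p = 0.36), and MEI4 (0.26 ± 0.16, adjusted p = 0.28), with REC107 at 0.23 ± 0.26 and HFM1 at -0.16 ± 0.22.

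The other lists did not pass camera for introns, with adjusted p between 0.18 and 0.79. In the cytoskeleton list ACT1 rose, and the other 7 of 8 features did not pass, with PFY1, the profilin gene, at 0.20 ± 0.15, COF1, the cofilin gene, at 0.16 ± 0.27 and TUB1, an alpha tubulin gene, at 0.15 ± 0.16. In the RNA processing list, 1 of 11 features rose, that of the RNA helicase gene DBP2 (0.73 ± 0.16, adjusted p = 0.023). The junction and exon ratios of DBP2 were also positive, at 0.56 ± 0.16 and 0.42 ± 0.21, without passing. Its intron minus junction was 0.17 ± 0.28 (adjusted p = 0.70), so a rise particular to the intron was not shown. LSM7 stood at 0.63 ± 0.29, LSM2 at 0.44 ± 0.17 and the mRNA export gene YRA1 at 0.28 ± 0.16, and none of these passed. Among genes with 2 introns, 3 of 12 features rose: both rows of RPL7B (0.84 ± 0.17 for the first) and the first row of RPL7A (0.75 ± 0.17, adjusted p = 0.024). The second row of RPL7A did not pass (0.37 ± 0.17, adjusted p = 0.15).

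No intron of the secretory traffic list passed (0 of 14), where YOP1 had 0.51 ± 0.17 (adjusted p = 0.066) and SEC17, which disassembles fusion complexes, 0.37 ± 0.16 (adjusted p = 0.13). SEC27, a coat protein of transport vesicles, had 0.32 ± 0.17 and BET1 0.32 ± 0.20. In the mitochondrial list 0 of 6 passed. COX4, a subunit of cytochrome oxidase, had 0.45 ± 0.15 (adjusted p = 0.067) with all 3 replicates between 0.44 and 0.46, and QCR10, QCR9 and ERV1 had 0.23 ± 0.19, -0.17 ± 0.15 and -0.12 ± 0.20. In the ubiquitin list 0 of 8 passed, with the conjugating enzyme genes UBC8, UBC5, UBC4 and UBC9 at 0.42 ± 0.23, 0.35 ± 0.24, 0.21 ± 0.18 and -0.10 ± 0.18. After centring on exon features, YOP1, SEC17, COX4 and LSM2 passed (adjusted p = 0.027, 0.040, 0.020 and 0.031).

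The next comparison asks whether spliced transcripts were lost. Junction signal fell for 1 of 248 features and rose for 0, with 29 lower and 4 higher at an unadjusted p under 0.05. The feature that fell was the second row of RPS22B, a protein of the small ribosomal subunit (-1.24 ± 0.18, adjusted p = 0.032, 2.36-fold lower), with -1.61, -1.07 and -1.04 in the 3 replicates. Its first row had -0.60 ± 0.17 (adjusted p = 0.19). Other ribosomal protein genes with low junction ratios did not pass: RPS18A at -1.07 ± 0.40, RPL27B at -0.90 ± 0.21 and RPL21A at -0.83 ± 0.22 (adjusted p from 0.19 to 0.28). The ACT1 junction had -0.36 ± 0.27 (adjusted p = 0.62), set by a single replicate, with -1.26, 0.09 and 0.08.

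The median junction ratio was -0.14 ± 0.07 (SD, n = 3), close to that of exon features, and it was -0.0073 after centring on them. The RPS22B call was lost after centring (adjusted p = 0.085) and without replicate 2. The number that passed was 11 without replicate 1 (7 lower and 4 higher) and 3 without replicate 3. The 2 lower calls of the snoRNA host list, adjusted over the list alone, were both of RPS22B. No list was set apart in this class, with a camera adjusted p of at least 0.18, but ribosomal protein genes were without replicate 1 (adjusted p = 0.000455). The difference between junctions of ribosomal protein genes and of other genes did not pass the permutation test (medians over genes of -0.12 and -0.08, a difference of -0.05, adjusted p = 0.092). Taken within each replicate the difference was 0.01, -0.17 and -0.27 (-0.14 ± 0.14, SD, n = 3). The permutation test passed without replicate 1, where these averaged -0.22.

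Outside RPS22B, which is also a gene with 2 introns, no junction of the fixed lists passed. For genes with 2 introns the largest ratios outside RPS22B were the second row of YOS1 (0.70 ± 0.28) and the first row of DYN2 (-0.35 ± 0.21). The export factor gene MTR2 had 0.58 ± 0.24 in 1 of its 6 rows and -0.40 ± 0.20 (n = 2) in another, and DBP2 had 0.56 ± 0.16 (adjusted p = 0.19). SNC1, a vesicle fusion protein, had -0.41 ± 0.16, the ubiquitin-like protein gene RUB1 -0.40 ± 0.21, MRPL44 of the mitochondrial ribosome -0.38 ± 0.18, TUB1 -0.32 ± 0.19, and the meiosis genes HFM1 and SPO1 0.20 ± 0.22 and -0.17 ± 0.16.

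Total mRNA was examined next, for whether the genes themselves were more or less expressed. Of 234 exon features 0 passed by limma, with 26 lower and 4 higher at an unadjusted p under 0.05 and a lowest adjusted p of 0.34. Ribosomal protein genes stood lower than other genes as a list by camera (adjusted p = 0.00094), but not with an estimated correlation (adjusted p = 0.87) or without replicate 3 (adjusted p = 0.076). Of 99 exon features 0 passed, over all exons or over the list alone, and the lowest were RPL2A (-0.73 ± 0.16), RPS19A (-0.63 ± 0.19), RPS18A (-0.60 ± 0.15) and RPL19A (-0.58 ± 0.16), all with an adjusted p of 0.34. Their difference from other genes was -0.14 (permutation p = 2e-05, adjusted p = 3e-05), and -0.06, -0.23 and -0.24 within the 3 replicates (-0.18 ± 0.10, SD, n = 3). Their median was -0.22 as deposited and -0.09 after centring.

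RNA processing genes stood above the other exon features (median 0.27, camera adjusted p = 0.0091; adjusted p = 0.87 with an estimated correlation and 0.076 without replicate 3). None of the 6 passed singly (0 calls). The highest were YRA1 (0.53 ± 0.18), MTR2 (0.44 ± 0.16) and DBP2 (0.42 ± 0.21), which act in mRNA export and RNA unwinding. MUD1, a protein of the U1 snRNP, went the other way at -0.37 ± 0.15. The 7 other lists were not set apart, with an adjusted p of at least 0.50. Their members with the largest ratios were PFY1 (-0.53 ± 0.17) and ACT1 (-0.33 ± 0.17) of the cytoskeleton, QCR10 (-0.43 ± 0.16) and ERV1 (-0.42 ± 0.17) of mitochondria, BET1 (-0.41 ± 0.23) and SAR1 (-0.36 ± 0.17) of secretory traffic, RPS22B (-0.41 ± 0.17) among snoRNA hosts and 2-intron genes, and UBC9 (-0.29 ± 0.16) and HFM1 (-0.29 ± 0.16) of the ubiquitin and meiosis lists.

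The last comparison takes differences between classes within a gene, in which the centring of an array cancels. Intron minus junction rose for 52 of 247 features and fell for 1. YIP3 had the highest value (1.98 ± 0.32, adjusted p = 3.73e-06), followed by SNR17B (1.93 ± 0.28), SNR17A (1.76 ± 0.28), TEF4 (1.76 ± 0.30) and RPS18A (1.75 ± 0.30), and ACT1 had 1.23 ± 0.29 (adjusted p = 0.0013). All 6 were above 0 in 3 of 3 replicates, which the rule required of all but ACT1, but YIP3 had 1.86, 0.63 and 3.45. The SD over replicates was 1.41 for YIP3, 1.14 for RPS18A and 1.03 for TEF4, against 0.13 for SNR17B. In this fit the variances were drawn strongly to a common value (57.2 prior degrees of freedom, against 5.83 in the fit of the classes). The SEs and p-values here therefore hardly reflect the replicate spread of a single feature. The feature that fell, RBS1 (-1.15 ± 0.31, adjusted p = 0.0053), was chosen after its values were seen, because it was the single lower call. It had -1.60, 0.33 and -2.19 in the 3 replicates and so did not keep 1 sign. Among ribosomal protein features 34 of 100 rose, 44 when adjusted over the list alone, and 8 of 11 snoRNA host features rose, RPS22B rows included (0.74 ± 0.28 and 1.20 ± 0.28).

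The median of intron minus junction was 0.43 ± 0.09 (SD, n = 3; 1.35-fold), and ribosomal protein genes exceeded other genes by 0.39 (permutation p = 1e-05, the smallest it can give, adjusted p = 2e-05). Within the 3 replicates they did so by 0.40, 0.41 and 0.27 (0.36 ± 0.08, SD, n = 3). Of the 59 introns that rose, 31 also passed here, but both tests use the same intron values, so the overlap is no independent support. Without replicate 3 only 2 features passed, and without replicate 1 there were 33. Without replicate 3, YIP3, TEF4, RPS18A and ACT1 missed the threshold.

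Intron minus exon rose for 72 of 246 features and fell for 0, with 58 of the 72 in ribosomal protein genes. Of the 59 introns that rose, 48 were among the 72, and here too the intron values are shared. Its median was 0.43 ± 0.14 (SD, n = 3). Ribosomal protein genes exceeded other genes by 0.45 (permutation p = 1e-05, the smallest it can give), and by 0.73, 0.44 and 0.28 within the 3 replicates (0.48 ± 0.23, SD, n = 3). No feature passed without replicate 1 (0 calls), and 45 passed without replicate 2. Junction minus exon had a median of 0.01 ± 0.04 (SD, n = 3). By limma 0 of 244 features passed, with 5 higher and 6 lower at an unadjusted p under 0.05, and the difference of ribosomal protein genes from others did not pass the permutation test (0.07, adjusted p = 0.078; 0.04 ± 0.04 over the replicates, SD, n = 3).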

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

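The tests of array centring, of missing spots, of a loss of spliced RNA, of crossed titles and of the direction of the replicate 1 cultures were chosen after the results were seen. Introns were higher in S2197F as a class, and 3 technical explanations were set against this. Array centring cannot move intron minus exon, whose median of 0.433 (SD 0.14 over 3 replicates) stayed above 0. Genomic DNA in the mutant RNA would raise introns of scarce transcripts at least as much as those of abundant ones, and DNA too scarce to show in them could not raise abundant ones. The median intron ratio of meiosis genes minus that of ribosomal protein genes was -0.432 (SD 0.32; -0.80, -0.30 and -0.20 in the replicates). The array with many missing spots belongs to replicate 2, and the medians of the other replicates averaged 0.298 (SD 0.11). This covers the shift of the class and not the calls of single introns. Without replicate 2, 2 introns passed by limma, against 59 with all replicates, 35 without replicate 1 and 47 without replicate 3. All 59 kept a ratio above 0 without replicate 2. No biological explanation was tested, and whether the signal comes from unspliced transcripts, splicing intermediates or excised introns stays open, since an intron feature detects all of these.

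Junction signal did not fall against exon signal while introns rose. The median of junction minus exon was 0.0147 (SD 0.040). This does not exclude a general loss of spliced RNA hidden by centring, which would lower both signals together, because most exon signal comes from spliced RNA.

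In the single-array values, which have no gene names and entered no comparison, replicate 1 ran against the other replicates as titled. The direction of these values is not known. The 2 arrays of a pair correlated at 0.062, 0.25 and 0.42 in replicates 1, 2 and 3, which does not settle it. If the values are ratios of mutant to wild type, the difference between the 2 arrays keeps dye bias and loses the mutant's effect. If they are ratios of the 2 dyes in a fixed order, dye bias cancels in the difference. It should then correlate positively between replicates. As titled, it correlated at -0.189 between replicates 1 and 2 and at -0.293 between replicates 1 and 3, against 0.127 between replicates 2 and 3. A response of the replicate 1 cultures in the opposite direction would turn the authors' combined intron ratios too, and these correlated positively with the other replicates (lowest r 0.428). Bias between print blocks was removed by centring each block, and the higher of the correlations remained at -0.167. Crossed titles of the 2 arrays would turn both correlations below 0, but these are the values (the higher -0.189, bootstrap SE 0.022) that raised the question, so this explanation stays open and untested.

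Arrays were also compared on 4 measures, where chance marks about 1 group in 20. The array of replicate 2 with the mutant in Cy5 lacked values for 28.5% of spots, against 0.933% to 4.87% on the others. The SD of log2 ratios on that array was 1.56, against 0.789 to 0.993. The array of replicate 2 with the mutant in Cy3 had 14 spots at the ceiling, against 4 to 6.

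With 3 replicates there are 4 sign patterns, too few for a share under 0.05. The highest count from any other pattern was 0, against 59 for introns, 1 for junctions, 0 for exons, 53 for intron minus junction, 72 for intron minus exon and 0 for junction minus exon. The number of patterns with a count as large, the real one included, was 1 for introns, junctions, intron minus junction and intron minus exon, and 4 for exons and junction minus exon.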

How the results depend on the processing

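Use of 1 value per gene, and removal of SNR17A and SNR17B, were chosen after the data were seen. Robust variances, complete genes only, the other thresholds and removal of SNR17A and SNR17B kept the counts over all features, and over ribosomal protein, other and snoRNA host introns, within 1.5 times. At an adjusted p under 0.1 the introns called went from 0 to 1 for secretory traffic and for mitochondria, and from 1 to 2 for RNA processing. Centring on exon features gave 91 introns (25 of them in other genes), 0 junctions, and medians of 0.43 for introns, -0.0073 for junctions and 0.0036 for exons, which follows from adding back the exon median. The junction call was also lost with each class fitted alone (0) and with 1 value per gene (0). Leaving out 1 replicate gave 2 to 47 introns, 0 to 36 of them in ribosomal protein genes and 2 to 16 in other genes, and 0 to 7 snoRNA host introns. It gave 0 to 11 junctions, 2 to 37 features for intron minus junction and 0 to 57 for intron minus exon. Ribosomal protein minus other junctions ran from -0.219 to -0.0859. Adjusted p of lists ran from 0.0279 to 0.263 for meiosis introns, 0.000455 to 0.792 for ribosomal protein junctions, 5.52e-06 to 0.0761 for ribosomal protein exons, and 0.0169 to 0.0761 for RNA processing exons. Fewer replicates leave fewer degrees of freedom, and other causes were not tested. With an estimated correlation the 5 lists that camera had called had an adjusted p of 0.868. Fry, which does not compare a list with other features, gave an adjusted p of 0.128 for ribosomal protein introns, 0.204 for snoRNA host introns, 0.261 for ribosomal protein exons and 0.204 for RNA processing exons, and turned the direction for meiosis introns (0.959). No fit by single dye orientation, from the single-array table, or with arrays as a random block was run, because its spots carry no gene names, and tests of intronless genes and intron sequences were not run. Signal over background was not analysed here, and in the simulated data shifts of 0.5 were recovered in part.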

Other observations

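HAC1, STO1 and TUB3 were chosen after their values were seen, and so was the comparison of classes across genes. HAC1, whose intron is removed by Ire1 and tRNA ligase and not by the spliceosome, had an intron ratio of 0.17 ± 0.17 (SE, n = 3, adjusted p = 0.50), a junction ratio of 0.30 ± 0.18 and an exon ratio of 0.45 ± 0.16, and none of these passed by limma. Its intron minus junction was -0.13 ± 0.28 (adjusted p = 0.77). Introns of genes other than ribosomal protein genes had a median of 0.15, and 15 of 150 rose, so the HAC1 intron did not stand apart from them. STO1, the large subunit of the nuclear cap-binding complex, had an intron that rose (0.85 ± 0.19, adjusted p = 0.023), with its junction at -0.01 ± 0.16. The tubulin genes TUB1 and TUB3 had intron ratios of 0.15 ± 0.16 and -0.02 ± 0.23, and neither passed.

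Across genes, no correlation of the mean intron ratio was detected with the mean exon ratio (r = 0.055, rho = -0.046, 232 features, permutation adjusted p = 0.40) or the junction ratio (r = 0.085, rho = 0.055, 247 features, permutation adjusted p = 0.36). Genes are not independent replicates.

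Many ribosomal proteins are made from A and B copies of a gene, whose exons are far more alike than their introns. The hypothesis that copies have more alike exon ratios than intron ratios, whether from shared sequence or shared regulation, was tested. Over the pairs, r was 0.16 for exons (45 pairs), -0.03 for introns (44 pairs) and -0.07 for junctions (45 pairs), each with a permutation adjusted p of 0.87. The exon correlation exceeded the intron correlation by 0.185, within its bootstrap SE of 0.218, so these pairs do not decide it.

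Across features, r between pairs of replicates was 0.64, 0.43 and 0.41 for introns, 0.19, 0.01 and 0.39 for exons, and 0.00152, 0.23 and 0.18 for junctions. By Spearman's rho, replicates 2 and 3 were at 0.30 for introns and 0.35 for exons. The smallest spread over features was in replicate 2, with an SD of 0.32 for introns against 0.55 and 0.52 in replicates 1 and 3.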
